A study of Homo sapiens with 9 samples.

How the data were processed

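RNA sequencing was done on 9 libraries of H9 cells, an established human embryonic stem cell (hESC) line. The 3 groups of 3 libraries were undifferentiated hESC, neural progenitor cells (NPC) at day 11 of a midbrain dopaminergic differentiation, and day 11 NPC that had been exposed to bafilomycin A1 (BafA1). Per the labels' protocols, the differentiation used LDN193189 at 200 nM and SB431542 at 10 µM, which block BMP and TGF-beta receptors, purmorphamine at 2 µM, which activates Hedgehog signalling, and CHIR99021 at 3 µM, which inhibits GSK3 and so activates WNT signalling. BafA1, an inhibitor of the vacuolar proton pump (V-ATPase) that stops lysosomal acidification and the clearance of autophagosomes, was given at 10 nM in exposures of 6 h. The labels list several windows of days for the exposure, and the window of the sequenced cells is not given in the sources used here. The labels call the libraries of a group biological replicates, and do not say whether cells of different groups were grown, harvested or sequenced together.

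Libraries were made from total RNA with a stranded mRNA kit, per the labels' protocols. Reads were trimmed with Trimmomatic and the genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool and their versions are not given in the sources used here. The authors deposited a table of whole-number read counts per gene, not normalised, with a column per library, per the file headers. The authors also deposited FPKM values per gene and library in a table for each group, per the file headers. In genes with 1 transcript the ratio of count to FPKM was within 0.5% of its median in 100% of genes of a library, against 22.5 to 29.3% of genes with more than 5 transcripts, in the 8 libraries set against the remaining one. Both tables therefore came from a single estimate of abundance, in which a count can be a sum over transcripts of a gene. Columns were matched to samples by their names, and the untreated NPC were the only group left for the columns named as control. No column was left unused, and 0 columns of other samples were present.

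The count table held 46427 genes, of which 19672 were protein-coding and 15054 had no count in any library. Total counts per library were 43124679 to 69703791, so that 1 count corresponded to 0.0143 to 0.0232 CPM (counts scaled by library total). The floor used for genes without counts was 3 counts per library, 0.043 to 0.0696 CPM. Floors and counting intervals (95%, exact) cover counting error only. Gene coordinates are 1-based positions from the RefSeq annotation of GRCh38.p14, joined by Entrez gene ID, and 44698 IDs matched. Genes with near-identical copies, among them metallothioneins, ribosomal protein genes with processed pseudogenes, and POU5F1, are uncertain where the counting could split reads between copies. The same holds for overlapping genes such as the mitochondrial ATP8 and ATP6.

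Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (20685 genes), libraries were scaled by TMM, and a quasi-likelihood model with 1 term per group was fitted to all 9 libraries (glmQLFit without robust estimation, glmQLFTest, two-sided). P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called changed at an adjusted p under 0.05. Unless stated otherwise, values of genes are TMM-scaled CPM as mean ± SD of n = 3 libraries, and changes are edgeR log2 fold changes with standard errors (SE). In that scaling 0 stands for the trimmed mean of all genes, so that a change is relative to most other genes and not an absolute amount of RNA.

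In all, 30 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated per list. The lists were also tested with fry, without comparison to other genes. The lists hold 681 entries, of which 680 matched a gene of the table. List members were also adjusted over the list alone. Fold changes against a group with no count in any library are lower bounds, computed against 3 counts per library. The gene lists, the tests, the samples in each fit and the alternatives listed next were chosen before the data were examined, as was the rule for named genes. For BafA1 NPC against control NPC and control NPC against hESC, the rule names the 8 largest rises and 8 largest falls. These were taken from called genes with no overlap between the 3 libraries of each group and at least 5 CPM in the higher group. The rule leaves out symbols of unnamed and antisense loci and every symbol ending in P and digits, whether or not the gene is a pseudogene. It also names up to 3 members of each list with the smallest adjusted p, and always DVL1, DVL2, DVL3, CTNNB1, AXIN2, LEF1, SQSTM1, MAP1LC3B, POU5F1, NANOG, SOX2, PAX6, SOX1, LMX1A, FOXA2, OTX2, EN1, SHH, DCX, TUBB3 and TH. Genes named outside it are said to have been chosen after their values were seen. Some genes that the rule names are not reported here.

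The alternatives were DESeq2 1.42.0 with its own size factors, DESeq2-style size factors in edgeR, library size alone, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries and a mean of 5 CPM), a fit of the 2 groups compared alone, the replicate number as a block, each library left out in turn, a test against a 1.5-fold change (glmTreat), a 2-fold minimum on the estimate, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean of at least 0.5 FPKM, or of all genes. Added after the data were seen were an offset that removes each library's spline trends on GC content and transcript length, alone and with the replicate block, the block together with an estimated correlation, counts of list members with each library left out, and 16 gene families. GC content and length were known for 97.1% of genes of at least 5 CPM. Principal components were computed on log2 CPM of genes of at least 5 CPM with a prior count of 2.

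The methods were tested on simulated data. In 5 simulations of the comparison of BafA1 NPC with control NPC over 20167 genes, edgeR recovered 6% of genes changed 1.25-fold, 31.2% of those changed 1.5-fold, 60.4% of those changed 2-fold and 83.2% of those changed 4-fold, and 31 of its 483 calls were false. These simulations changed 250 genes at each fold over all 5 runs, against 8586 genes called in the data. The share recovered depends on the number of changed genes, so it need not hold for the data. Camera found the shifted list in 5 of 5 simulations and called 0 of 145 unshifted lists. Genes were drawn independently of each other there, so this does not test camera on lists whose members vary together. With a strong GC trend planted over 20324 genes, the uncorrected test made 8083 false calls and the corrected one 8, with 190 of 200 genes changed 2-fold recovered. XIST and genes of the Y chromosome were left out of the tables of genes. Tables were prepared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.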

Results

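Messenger RNA was measured in 9 libraries of H9 hESC and of NPC derived from them. The groups were undifferentiated hESC, control NPC at day 11 and BafA1-treated NPC at day 11, with 3 libraries each. Library totals were 55706968 to 66544642 counts in hESC, 49479733 to 56054194 in control NPC and 43124679 to 69703791 in BafA1 NPC. The series concerns autophagy in neuronal differentiation and the WNT pathway protein Dishevelled (DVL). Its main comparison is BafA1 NPC with control NPC, and control NPC against hESC gives the scale of the differentiation itself.

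The groups were separated on the first 2 principal components. The first held 87.3% of the variance and set hESC (114 to 116) apart from NPC (-62.2 to -50.5). The second held 8.65% and set control NPC (-37.9 to -24.5) apart from BafA1 NPC (23.1 to 38.4). Replicates differed by far more than counting noise, with a chi-square of 12.5 to 85.5 per degree of freedom, and no library was a copy of another. Messenger RNA of the mitochondrial genome made up 4.19 ± 0.432% of counts in hESC, 3.04 ± 0.115% in control NPC and 2.09 ± 0.112% in BafA1 NPC (SD, n = 3). Ribosomal protein genes made up 7.77 ± 0.464%, 7.87 ± 0.898% and 10.3 ± 1.62%. Each library's deviation from the mean of all 9 correlated across genes with GC content, at Spearman's rho of 0.066 to 0.176 in hESC, -0.398 to -0.096 in control NPC and -0.009 to 0.099 in BafA1 NPC. Genes are not independent replicates for such a correlation.

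**Figure D1:**
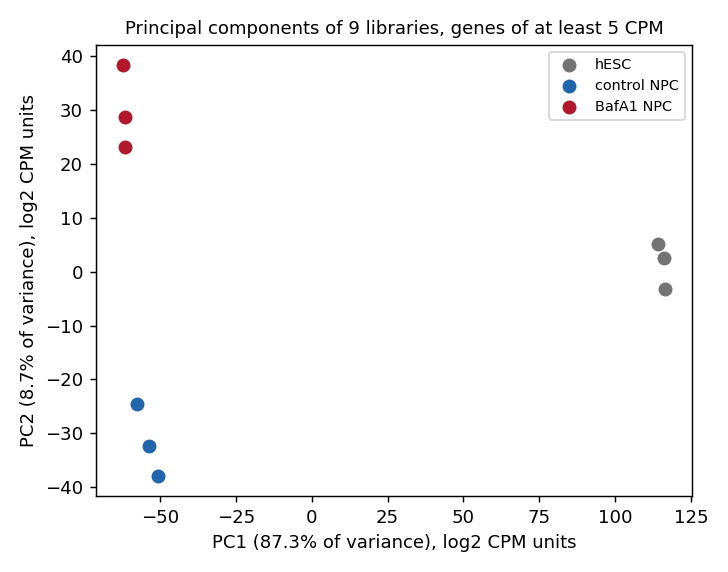
Scores of the 9 libraries on the first 2 principal components of log2 CPM, for genes of at least 5 CPM, with a point per library coloured by group. The hESC libraries lie at 114 to 116 on the first component, and on the second the control NPC (-37.9 to -24.5) and BafA1 NPC (23.1 to 38.4) do not overlap.

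The first comparison asked what differentiation to day 11 changed. POU5F1, the core pluripotency factor (chromosome 6, 31164337 to 31170682, GRCh38), fell from 2285 ± 139 CPM in hESC to no count in control NPC (SD, n = 3), at least 42505-fold lower. NR2F1, a nuclear receptor of the neural tube (chromosome 5, 93583222 to 93594611), rose from no count to 159 ± 15.1 CPM, at least 3123-fold higher. The floor plate gene SHH, which encodes Sonic hedgehog, rose from 1.64 ± 0.459 to 215 ± 90.4 CPM, and LMX1A, a midbrain floor plate transcription factor, from 0.11 ± 0.101 to 77.3 ± 17.7 CPM. In total 6816 genes were higher and 6529 lower in control NPC at an edgeR adjusted p under 0.05, of 20685 tested. Of these, 3578 were higher and 3463 lower by at least 2-fold in the estimate.

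Large rises by the fixed rule were from hESC libraries without a count. Besides NR2F1 they included GASK1B (at least 1958-fold), the protease inhibitor A2M (at least 1545-fold), the forkhead factor FOXA1 (at least 1030-fold), the matrix protein lumican, LUM (at least 636-fold), PLSCR5 (at least 588-fold) and the homeobox gene MEIS1 (at least 440-fold). The largest falls, to control libraries without a count, were in POU5F1, the NODAL co-receptor TDGF1 (at least 8596-fold lower), the kinase LCK (at least 1367-fold), the long noncoding RNA LNCPRESS2 (at least 1094-fold), the eye field factor SIX6 (at least 923-fold), FOXD3 (at least 757-fold) and PRDM14 (at least 602-fold). ZSCAN10, a zinc finger gene of pluripotent cells, had few counts in control NPC, and its ratio was 11229-fold with a 95% counting interval of 3842 to 54452.

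All 23 tested pluripotency genes fell, and all 23 fell adjusted over the list alone (median log2 change -8.18, or -6.94 with genes at their bound, camera adjusted p = 3.51e-77, adjusted p = 8.29e-04 with an estimated correlation). ESRG, a transcript of pluripotent cells, fell from 996 to 0.184 CPM, and NANOG from 95.8 ± 0.22 to 0.229 ± 0.202 CPM. Of 24 neural progenitor genes 21 rose and 2 fell, with the same counts adjusted over the list alone (median 5.86, or 3.58 at the bounds, camera adjusted p = 1.44e-27, adjusted p = 8.29e-04 with an estimated correlation). Examples were NR2F2 (log2 change 9.21 ± 0.17 SE), the cell cycle regulator PLAGL1 (6.25 ± 0.12) and DACH1 (7.97 ± 0.17). The early neural factor SOX1 rose to 23.9 ± 5.52 CPM (9.91 ± 0.40). PAX6, which marks dorsal and forebrain progenitors, had no count in hESC and 0.38 ± 0.163 CPM in control NPC, at least 7.48-fold higher, a call lost with limma on log2(FPKM + 1) of all genes (adjusted p = 0.210). SOX2, shared by pluripotent and neural cells, rose by 0.34 ± 0.09, and this call was lost after removal of GC and length trends (0.21, adjusted p = 0.0710).

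Of 24 genes of the midbrain floor plate and dopaminergic lineage 19 rose and 1 fell, also adjusted over the list alone (median 6.12, or 4.69 at the bounds, camera adjusted p = 3.43e-11, but adjusted p = 0.155 with an estimated correlation). MSX1 rose by 7.28 ± 0.32 and LMX1A by 9.40 ± 0.44. FOXA2, a floor plate factor, rose from 62.3 ± 3.77 to 101 ± 12.1 CPM, and OTX2, of the forebrain and midbrain, from 68.5 ± 6.31 to 122 ± 43.4 CPM, a call lost with limma on log2(FPKM + 1) of all genes (adjusted p = 0.0543). The midbrain gene EN1 rose from no count to 4.95 ± 1.73 CPM, at least 97.3-fold. TH, the enzyme that makes the dopamine precursor L-DOPA, had no count in hESC and 0.0225 ± 0.039 CPM in control NPC, both at or under the floor of 3 counts. Of 11 hindbrain and spinal genes 10 rose, also adjusted over the list alone (median 7.42, or 3.64 at the bounds, camera adjusted p = 2.82e-08, adjusted p = 0.00874 with an estimated correlation), among them MEIS2 (10.25 ± 0.29). Of 11 genes of the ventral neural tube outside the floor plate 8 rose and 3 fell, also adjusted over the list alone (median 7.42, or 4.23 at the bounds, camera adjusted p = 2.80e-04, but adjusted p = 0.158 with an estimated correlation). Of 14 forebrain genes 6 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.886). FEZF2 rose by 7.60 ± 0.22, while SIX6 was lost.

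Of 15 Hedgehog genes 12 rose and 1 fell, 13 and 1 adjusted over the list alone (median 1.28, camera adjusted p = 9.59e-06, adjusted p = 0.0247 with an estimated correlation). The Hedgehog call was lost with an estimated correlation and the replicate block together (adjusted p = 0.187). The receptor PTCH1, itself a target, rose by 2.85 ± 0.14. Of 21 WNT beta-catenin target genes 15 rose and 6 fell, also adjusted over the list alone (median 1.93, camera adjusted p = 1.59e-06, but adjusted p = 0.158 with an estimated correlation). AXIN2, a feedback inhibitor of the pathway, rose by 2.60 ± 0.11, the transcription factor LEF1 by 8.22 ± 0.25 and the inhibitor NKD1 by 5.37 ± 0.16. Of 21 WNT ligands, R-spondins and WLS 14 rose and 3 fell (median 1.87, camera adjusted p = 8.03e-04, but adjusted p = 0.158 with an estimated correlation), and of 20 WNT antagonists 12 rose and 7 fell (median 1.33, camera adjusted p = 0.0220, but adjusted p = 0.498 with an estimated correlation), with the same counts adjusted over the list alone. The WNT carrier gene WLS rose from 0.915 to 343 CPM, while SFRP2, a secreted antagonist, fell by 3.58 on the log2 scale. The WNT receptors, DVL and destruction complex were not called as a list (12 of 27 rose, 9 fell, also adjusted over the list alone, adjusted p = 0.886). DVL2 rose from 59 ± 2.91 to 90.6 ± 0.773 CPM (0.62 ± 0.07), DVL1 fell from 55.7 ± 1.64 to 41.5 ± 2.03 CPM (-0.43 ± 0.08) and DVL3 was at 96.7 ± 3.91 and 99.6 ± 3.36 CPM (adjusted p = 0.636). CTNNB1, which encodes beta-catenin, rose by 0.41 ± 0.09. After removal of GC and length trends DVL1 (-0.13, adjusted p = 0.135) and CTNNB1 (0.15, adjusted p = 0.163) were no longer called, and DVL3 was (0.24, adjusted p = 0.0134).

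Among the other lists, 21 of 28 neuronal genes rose and 4 fell (median 1.64, camera adjusted p = 0.0126, but adjusted p = 0.469 with an estimated correlation). MAP2 rose by 3.87 ± 0.09, DCX by 1.52 ± 0.22 and TUBB3 by 0.71 ± 0.11, while SCG3 fell by 3.94. Cholesterol synthesis genes fell in 23 of 25 cases and 2 rose (median -1.14, camera adjusted p = 1.59e-06, but adjusted p = 0.283 with an estimated correlation). Of 21 genes of mesoderm and mesenchyme 13 rose and 7 fell (median 2.85, camera adjusted p = 2.37e-08, but adjusted p = 0.0768 with an estimated correlation), among them the collagen gene COL3A1, from 0.0227 to 88.4 CPM. Of 17 epithelial genes 10 fell and 6 rose (median -1.56, camera adjusted p = 2.07e-08, adjusted p = 0.0189 with an estimated correlation), and E-cadherin, CDH1, fell from 346 to 0.285 CPM. Of 19 p53 targets 16 rose and 2 fell (1 without control replicate 2 or 3 or any hESC replicate; median 0.90, camera adjusted p = 1.69e-04, but adjusted p = 0.469 with an estimated correlation), and of 20 immediate early genes 13 fell and 5 rose (median -0.66, camera adjusted p = 0.00242, but adjusted p = 0.469 with an estimated correlation). All counts of this paragraph were the same adjusted over the list alone. Of 31 lysosomal genes 15 rose and 6 fell, with the same counts again (median 0.23, camera adjusted p = 0.0416, but adjusted p = 0.550 with an estimated correlation). That call was lost without hESC replicate 2 (adjusted p = 0.0646) or 3 (0.0526) or control replicate 1 (0.0738). The autophagy receptor gene SQSTM1 fell by 0.34 on the log2 scale (adjusted p = 0.0273), a call lost without hESC replicate 1 (0.0915) or 3 (0.0523), without control replicate 2 (0.0552) or 3 (0.105) and under scaling by library size alone (0.0825) or removal of GC and length trends (0.333). MAP1LC3B, which encodes the autophagosome protein LC3B, rose by 0.42 ± 0.09.

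The remaining lists were not called in this comparison, with counts that were the same adjusted over the list alone. Members that rose and fell numbered 10 and 9 of 20 for Notch (adjusted p = 0.985), 12 and 7 of 22 for BMP and TGF-beta targets (0.249), 13 and 3 of 21 for V-ATPase subunits (0.0830), 13 and 16 of 40 for autophagy machinery (0.900) and 5 and 7 of 16 for iron handling (0.294). They numbered 9 and 8 of 26 for hypoxia response (0.923), 9 and 7 of 25 for the integrated stress and unfolded protein response (0.985), 4 and 17 of 30 for proliferation (0.168), 7 and 9 of 20 for neural crest (0.844), 5 and 7 of 12 for endoderm (0.886), 4 and 7 of 14 for glia (0.330) and 0 and 8 of 13 for mitochondrially encoded transcripts (0.168). Without control replicate 2, hESC replicate 1 or hESC replicate 2, the hypoxia genes that rose numbered 5. Without hESC replicate 2 or control replicate 2 the mitochondrial genes that fell also numbered 5, and without hESC replicate 2 or control replicate 1 the glia genes that rose numbered 2. The mitochondrial list was called after removal of GC and length trends (adjusted p = 0.0385), but its adjusted p was 0.817 with an estimated correlation and no such removal. Without control replicate 3 or hESC replicate 1 the BMP and TGF-beta targets were called (adjusted p = 0.0413 and 0.0321), and without control replicate 3 the V-ATPase subunits were (0.0434), as they were under library size alone (0.0389). With all libraries and an estimated correlation neither list was called (camera adjusted p = 0.574 and 0.550). The hypoxia list had a positive median (0.26) and a test in the direction of lower expression, and the neural crest list did too (0.09). Mean and test were positive for the autophagy list (mean 0.06), whose median was not above 0.

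The second comparison asked what BafA1 changed in NPC. NDRG1, a stress-responsive gene (chromosome 8, 133237175 to 133297252), rose from 43.1 ± 13.7 to 348 ± 117 CPM, and the glucose transporter gene SLC2A1 from 495 ± 40.5 to 1944 ± 377 CPM (SD, n = 3). HMGCS1, an early enzyme of the mevalonate pathway, fell from 340 ± 81.7 to 96.1 ± 4.32 CPM, and the replication clamp gene PCNA from 274 ± 20.4 to 108 ± 16.4 CPM. In total 4309 genes were higher and 4277 lower at an edgeR adjusted p under 0.05, and 1318 were higher and 940 lower by at least 2-fold in the estimate. Under scaling by library size alone the median of all genes shifted by -0.13 and the calls split into 3104 higher and 5681 lower; with limma on log2(FPKM + 1) they split into 2590 and 5170.

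The largest rise by the fixed rule was in NPPB, which encodes a natriuretic peptide, from 0.354 ± 0.0961 to 7.86 ± 2.82 CPM (log2 change 4.46 ± 0.40 SE, adjusted p = 1.97e-05). The metallothionein genes MT1E (4.34 ± 0.39) and MT1X (2.99 ± 0.16) encode small metal-binding proteins that share much of their sequence. SLAMF9 rose by 4.31 ± 0.52, the growth factor gene PDGFB by 3.48 ± 0.22, NDRG1 by 3.01 ± 0.30, the transcriptional repressor BHLHE40 by 2.87 ± 0.19 and the imprinted noncoding RNA H19 by 2.86 ± 0.16. The largest falls were in CABLES1 (-2.64 ± 0.31, from 5.85 ± 1.69 to 0.954 ± 0.43 CPM), the transcription factors EBF2 (-2.48 ± 0.30) and MECOM (-2.38 ± 0.34), the WNT receptor FZD10 (-2.33 ± 0.33), the S-phase cyclin CCNE2 (-2.33 ± 0.23), the ecto-enzyme NT5E (-2.19 ± 0.25), the matrix protein PRELP (-2.17 ± 0.32) and the small GTPase RHOJ (-2.14 ± 0.16).

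**Figure D2:**
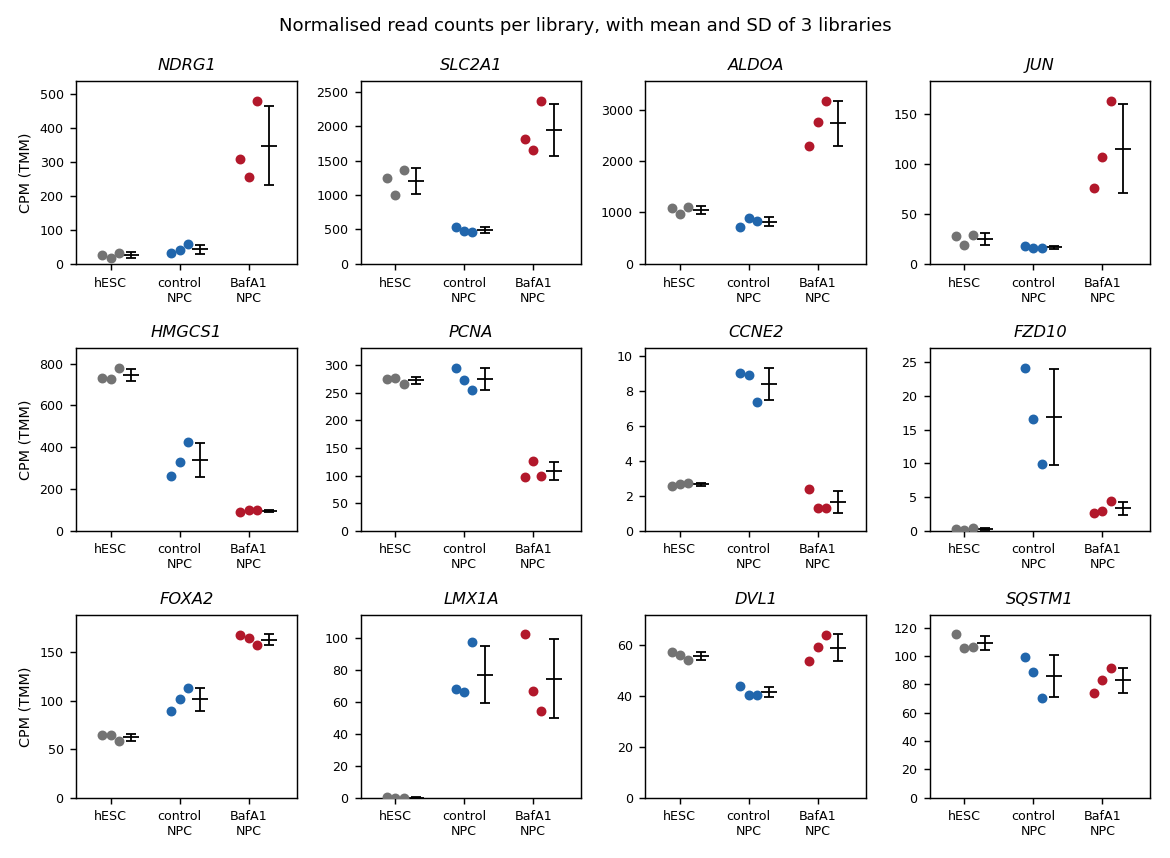
TMM-scaled CPM of 12 genes in each of the 9 libraries, with a point per library and a bar at the mean with the SD of n = 3. NDRG1, SLC2A1, ALDOA and JUN were higher and HMGCS1, PCNA, CCNE2 and FZD10 lower in each BafA1 library than in each control library, as 10% of unchanged genes would be in one direction or the other, while LMX1A and SQSTM1 overlapped.

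Of 26 hypoxia response genes 25 rose, and all 26 rose adjusted over the list alone (median 1.501, camera adjusted p = 2.17e-26, but adjusted p = 0.326 with an estimated correlation). The exception over all genes was CA12 (0.65, adjusted p = 0.0641, named after its value was seen). SLC2A3, a glucose transporter gene, rose by 2.28 ± 0.19, SLC2A1 by 1.97 ± 0.16 and the glycolytic enzyme gene ALDOA by 1.74 ± 0.13, from 819 ± 85.8 to 2738 ± 437 CPM. Of 25 genes of the integrated stress and unfolded protein response 15 rose and 3 fell, also adjusted over the list alone (median 0.59, camera adjusted p = 5.26e-05, but adjusted p = 0.561 with an estimated correlation). The secreted glycoprotein gene STC2 rose by 1.26 ± 0.13, ATF5 by 1.21 ± 0.13 and PPP1R15A, whose product restarts translation, by 1.51 ± 0.16. The 3 that fell, named after their values were seen, were the endoplasmic reticulum genes CRELD2 (-0.90), SDF2L1 (-0.66) and DNAJC3 (-0.29). Of 20 immediate early genes 12 rose and 2 fell, 13 and 2 adjusted over the list alone (median 0.77, camera adjusted p = 1.32e-05, but adjusted p = 0.365 with an estimated correlation), among them JUN (2.80 ± 0.25), MYC (2.21 ± 0.14) and IER3 (1.84 ± 0.15).

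Of 25 genes of cholesterol synthesis and uptake 17 fell and none rose, also adjusted over the list alone (median -0.56, camera adjusted p = 2.63e-10, but adjusted p = 0.347 with an estimated correlation). HMGCS1 fell by 1.82, the isomerase gene IDI1 by 1.53 and ACAT2 by 1.52 on the log2 scale. Of 30 proliferation genes 18 fell and 2 rose, 20 and 2 adjusted over the list alone (median -0.50, camera adjusted p = 1.91e-07, but adjusted p = 0.365 with an estimated correlation). CCNE2, PCNA (-1.35 ± 0.11) and the helicase subunit gene MCM6 (-1.07 ± 0.11) fell. The 2 that rose, named after their values were seen, were PLK1 (0.29) and CDC20 (0.29), which act in mitosis; their number was 4 without BafA1 replicate 1, 1 without BafA1 replicate 2 or control replicate 3 and 0 without control replicate 2. Of 13 mitochondrially encoded genes 9 fell, 10 adjusted over the list alone (median -0.56, camera adjusted p = 4.30e-05, but adjusted p = 0.561 with an estimated correlation), beside the lower share of mitochondrial messenger RNA given above. The ATP synthase genes ATP8 and ATP6, which overlap, fell by 1.59 and 1.33, and ND2, of respiratory complex I, by 0.93.

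Of 22 BMP and TGF-beta targets 14 rose and 3 fell, also adjusted over the list alone (median 0.72, camera adjusted p = 4.29e-04, but adjusted p = 0.326 with an estimated correlation). The members with the smallest p encode inhibitors of the pathway: the BMP antagonists NOG (2.05 ± 0.21) and GREM1 (1.71 ± 0.16, from 39.1 ± 9.91 to 128 ± 12.8 CPM) and the inhibitory protein SMAD7 (1.44 ± 0.15). The 3 that fell, named after their values were seen, were SKIL (-0.55) and the BMP-induced genes ID2 (-0.55) and ID3 (-0.37), and without control replicate 1 or 2 only 1 fell. Of 20 Notch genes 11 rose and 3 fell, 12 and 3 adjusted over the list alone (median 0.40, camera adjusted p = 0.00976, but adjusted p = 0.356 with an estimated correlation). The ligand genes JAG1 (0.96 ± 0.10) and JAG2 (1.10 ± 0.15) and the effector HES4 (1.62 ± 0.19) rose. The Notch call was lost after removal of GC and length trends (adjusted p = 0.105), and without BafA1 replicate 3, control replicate 1 or control replicate 2 only 1 member fell. Of 17 epithelial genes 9 rose and 1 fell, 11 and 1 adjusted over the list alone (median 0.58, or 0.48 at the bounds, camera adjusted p = 0.00558, but adjusted p = 0.326 with an estimated correlation). The keratin gene KRT19 rose from 48.7 ± 9.27 to 124 ± 12.1 CPM, against 139.8 ± 13.7 CPM in hESC, while CDH1 rose from 0.285 ± 0.0476 to 1.01 ± 0.323 CPM, far below its 346 ± 19.3 CPM in hESC; the CDH1 call was lost with limma on log2(FPKM + 1) (adjusted p = 0.150). These made 9 lists called, and regrouping the same 6 libraries called up to 14. Each regrouping mixed libraries of both groups and so kept part of any difference between them. The number of lists by itself is thus no evidence for or against a difference between the groups.

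**Figure D3:**
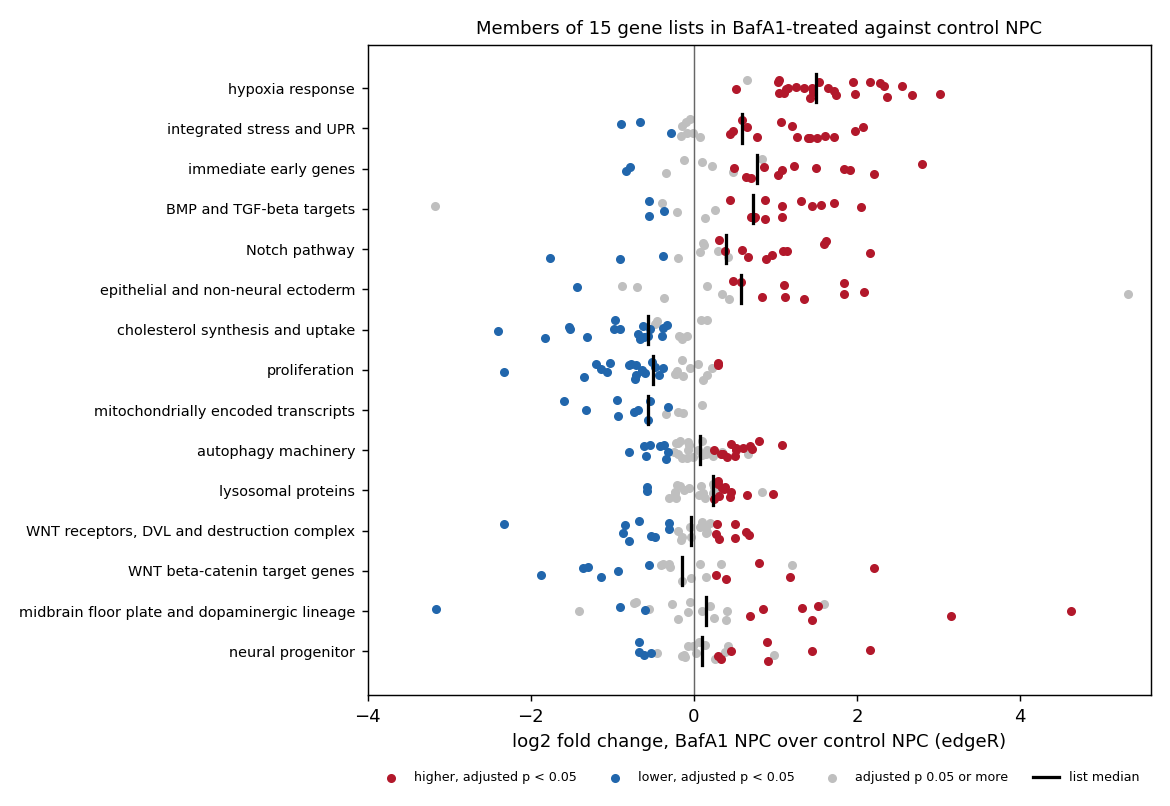
Log2 fold changes of the members of 15 gene lists, BafA1 NPC over control NPC, with a point per gene coloured by its edgeR call and a vertical bar at the list median. Medians were 1.501 for the hypoxia response, -0.56 for cholesterol synthesis and -0.50 for proliferation, and members of the WNT, autophagy and midbrain lists lay on both sides of 0.

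The series asks about DVL and WNT signalling, of which messenger RNA but not protein was measured here. The DVL genes all had positive estimates, and genes of the wider pathway moved in both directions. DVL1 (chromosome 1, 1335278 to 1349418) rose from 41.5 ± 2.03 to 59 ± 5.15 CPM (0.51 ± 0.08, adjusted p = 6.30e-04), DVL2 (chromosome 17, 7225342 to 7234517) from 90.6 ± 0.773 to 112 ± 4.94 CPM (0.30 ± 0.07, adjusted p = 0.00640) and DVL3 (chromosome 3, 184155377 to 184173614) from 99.6 ± 3.36 to 121 ± 5.24 CPM (0.28 ± 0.07, adjusted p = 0.0108). Under scaling by library size alone DVL2 (0.18, adjusted p = 0.0663) and DVL3 (0.15, adjusted p = 0.135) were not called, nor after removal of GC and length trends (0.13 and 0.14, adjusted p = 0.140 and 0.145). DVL1 stayed called, at 0.38 under library size alone and at 0.23 after removal of these trends. CTNNB1 fell from 761 ± 53.3 to 544 ± 19.9 CPM (-0.48 ± 0.09). Of 27 WNT receptors, DVL and destruction complex genes 7 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.735). The destruction complex scaffold APC fell by 0.87 and BTRC, which marks beta-catenin for degradation, by 0.79, while TCF7L1 rose by 0.68.

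Of 21 WNT beta-catenin target genes 5 rose and 6 fell, 5 and 7 adjusted over the list alone (adjusted p = 0.799). MYC rose, and APCDD1, an inhibitor of the pathway, fell from 281 ± 59.7 to 76.6 ± 22.8 CPM (-1.88 ± 0.20). TCF7 fell by 1.30, while AXIN2 was at 154 ± 22.9 and 150 ± 3.65 CPM (adjusted p = 0.797; the estimate was 0.08 without control replicate 1). LEF1 was at 52.7 ± 12.2 and 40.6 ± 0.684 CPM (-0.38 ± 0.15, adjusted p = 0.0613). It was called lower without control replicate 3 (-0.55, adjusted p = 0.00249), under library size alone (-0.50, adjusted p = 0.0195) and after removal of GC and length trends (-0.39, adjusted p = 0.0491). Of 21 WNT ligands, R-spondins and WLS 6 rose and 4 fell, 7 and 5 adjusted over the list alone (adjusted p = 0.565), with WNT7A (2.69 ± 0.36) and WLS (0.86 ± 0.10) higher and WNT4 (-1.87 ± 0.26) lower. Of 20 WNT antagonists 8 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.691), with FRZB lower (-1.20 ± 0.15).

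Genes of autophagy and lysosomes also moved in both directions. Their proteins and the clearance of autophagosomes were not measured. Of 40 autophagy genes 13 rose and 8 fell, 14 and 9 adjusted over the list alone (adjusted p = 0.565). The receptor gene OPTN rose by 1.08 ± 0.13 and GABARAPL1, of the LC3 family, by 0.71 ± 0.10, while ATG5, needed to lipidate LC3, fell by 0.53. SQSTM1 was at 86.2 ± 14.8 and 83 ± 8.79 CPM (adjusted p = 0.748) and MAP1LC3B at 87.5 ± 3.87 and 94.1 ± 11.2 CPM (adjusted p = 0.392). The sign of the SQSTM1 estimate changed without BafA1 replicate 1 or control replicate 1, and that of MAP1LC3B under scaling by library size alone. Of 31 lysosomal genes 11 rose and 2 fell, also adjusted over the list alone (median 0.24, adjusted p = 0.138), and the list was called without control replicate 1 (adjusted p = 0.0350) and by fry (0.0408). Its camera adjusted p was 0.830 with an estimated correlation and 0.420 after removal of GC and length trends. The number that rose was 6 without control replicate 2 and 7 without control replicate 3 or BafA1 replicate 3, and 4 fell without either of the last. The hydrolase gene GAA rose from 40.9 ± 1.66 to 80.1 ± 2 CPM (0.97 ± 0.08) and PSAP, which encodes activators of lipid hydrolases, by 0.65 ± 0.09. Of 21 subunits and accessory proteins of the V-ATPase, the target of BafA1, 6 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.735). ATP6V0A2 fell from 27.3 ± 1.82 to 12.9 ± 0.757 CPM and ATP6V1H rose by 0.57 ± 0.08. Of 16 iron genes 4 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.976, with a median of 0.07 and a test in the other direction). The transferrin receptor gene TFRC fell from 167 ± 13 to 103 ± 8.94 CPM and the haem oxygenase gene HMOX1 rose from 8.69 ± 3.35 to 28.2 ± 10.2 CPM.

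None of the lists of regional and neural genes was called by camera. By fry, which asks whether a list changed at all and not whether it changed more than other genes, the hindbrain and spinal list was lower (adjusted p = 0.00151) and the ventral list higher (0.0324). Of 24 genes of the midbrain floor plate and dopaminergic lineage 7 rose and 3 fell, also adjusted over the list alone (median 0.15, adjusted p = 0.565). FOXA2 rose from 101 ± 12.1 to 163 ± 5.29 CPM (0.68 ± 0.10). TH rose from 0.0225 ± 0.039 to 0.632 ± 0.127 CPM (4.62 ± 0.82, adjusted p = 0.00160), a low level whose fold is uncertain because counts were found in only 1 control library. LMX1A was at 77.3 ± 17.7 and 74.7 ± 24.9 CPM (adjusted p = 0.894), SHH at 215 ± 90.4 and 188 ± 19.1 CPM (adjusted p = 0.566) and OTX2 at 122 ± 43.4 and 145 ± 44.4 CPM (adjusted p = 0.418). EN1 was at 4.95 ± 1.73 and 3.01 ± 0.597 CPM (-0.71 ± 0.29, adjusted p = 0.0716). Without control replicate 3 EN1 was called lower (-0.97, adjusted p = 0.00844) and OTX2 higher (0.58, adjusted p = 0.0358), and EN1 was also called under library size alone (-0.85, adjusted p = 0.0355) and after removal of GC and length trends (-0.76, adjusted p = 0.0492). Without control replicate 3 the estimates of LMX1A (0.15) and SHH (0.15) were positive.

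Of 11 hindbrain and spinal genes 1 rose and 5 fell, also adjusted over the list alone (median -0.38, adjusted p = 0.138), and 3 fell without control replicate 1 or 2 or BafA1 replicate 2 or 3. HOXB1 fell from 2.24 ± 0.726 to 0.22 ± 0.124 CPM (-3.30 ± 0.44), HOXB2 from 2.89 ± 0.513 to 0.464 ± 0.118 CPM (-2.64 ± 0.30) and HOXA2 by 0.87. Of 14 forebrain genes 4 rose, 2 adjusted over the list alone (adjusted p = 0.326), and 1 rose without BafA1 replicate 2 or control replicate 2 and 2 without BafA1 replicate 1 or control replicate 1. FEZF2 rose from 16.7 to 42.3 CPM (1.34 ± 0.13). Of 11 ventral genes 3 rose and 1 fell, 2 and 0 adjusted over the list alone (adjusted p = 0.272), with OLIG2 (1.23 ± 0.17) and NKX6-2 (1.63 ± 0.27) higher. Of 24 neural progenitor genes 7 rose and 4 fell, 8 and 4 adjusted over the list alone (median 0.10, adjusted p = 0.627), and 4 rose without control replicate 1 or 2. The intermediate filament gene VIM rose from 5104 ± 469 to 9578 ± 1710 CPM (0.91 ± 0.15). SOX2 rose by 0.34 ± 0.09 and was not called under library size alone (0.21, adjusted p = 0.0552). SOX1 fell by 0.67 (adjusted p = 0.0202), a call lost without BafA1 replicate 1 (0.0709) or 3 (0.0515) or control replicate 1 (0.0889) or 2 (0.0632). PAX6 was at 0.38 ± 0.163 and 1.04 ± 0.516 CPM (adjusted p = 0.0357), a call lost without any 1 of control replicates 1 (0.101), 2 (0.0577) and 3 (0.0546) or BafA1 replicates 1 (0.149) and 3 (0.0685). Of 28 neuronal genes 7 rose and 1 fell, 7 and 0 adjusted over the list alone (adjusted p = 0.414). TUBB3 was at 263 ± 44 and 260 ± 3.7 CPM (adjusted p = 0.923) and DCX at 27.5 ± 3.69 and 22.6 ± 8.56 CPM (adjusted p = 0.301). Without BafA1 replicate 1 DCX was called lower (-0.62, adjusted p = 0.00571) and 4 neuronal genes fell.

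The other lists were not called either. Members that rose and fell numbered 5 and 4 of 23 for pluripotency (adjusted p = 0.687; 5 and 4 adjusted over the list alone), with POU5F1 at no count and 0.00607 ± 0.0105 CPM and NANOG at 0.229 ± 0.202 and 0.0894 ± 0.0857 CPM. LIN28A, an RNA-binding protein gene kept in early progenitors, rose from 537 to 786 CPM. For Hedgehog genes the numbers were 5 and 5 of 15 (adjusted p = 0.837; 5 and 6 adjusted over the list alone; median -0.15, mean 0.03), and 3 rose without BafA1 replicate 3 or control replicate 1 or 2. For p53 targets they were 5 and 5 of 19 (0.735; 6 and 5), for neural crest 4 and 3 of 20 (0.735; 4 and 2), for mesoderm and mesenchyme 8 and 4 of 21 (0.780; 8 and 4), for endoderm 4 and 2 of 12 (0.627; 5 and 2; median 0.36, mean -0.02) and for glia 4 and 3 of 14 (0.846; 5 and 4). Without control replicate 2, 3 p53 targets rose and 3 fell, as 3 rose without BafA1 replicate 3 and 3 fell without BafA1 replicate 2. Only 2 neural crest genes rose without BafA1 replicate 3, 2 endoderm genes without BafA1 replicate 1 or 2 or control replicate 1, and 2 pluripotency genes fell without control replicate 2. LUM fell from 32.3 ± 2 to 10.2 ± 1.76 CPM and the contractile gene ACTA2 rose from 107 to 213 CPM, both of the mesenchyme list, and CXCR4, of the endoderm list, rose from 93.2 ± 27 to 218 ± 36.5 CPM.

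The third comparison set BafA1 NPC against hESC. POU5F1 and NANOG were as low in BafA1 NPC as given above, LIN28A was at 1176 CPM in hESC and 786 CPM in BafA1 NPC, and 22 of 23 pluripotency genes fell, 23 adjusted over the list alone. Of 24 neural progenitor genes 20 rose and 2 fell, and of 24 midbrain genes 21 rose and 2 fell, also adjusted over the list alone. Of 26 hypoxia genes 24 rose against hESC and 1 fell, 24 and 1 adjusted over the list alone (camera adjusted p = 1.41e-05, but adjusted p = 0.413 with an estimated correlation). In total 7353 genes were higher and 7204 lower.

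The last comparison asked whether BafA1 moved NPC along the path from hESC to NPC. On an axis with the hESC mean at 0 and the mean of all NPC at 1, control NPC lay at 0.986 ± 0.0182 and BafA1 NPC at 1.01 ± 0.0113 (SD, n = 3). The control and BafA1 libraries both helped to set this axis. A group further along it lies at a larger distance from hESC, which need not be further differentiation. An exact two-sided permutation test gave p = 0.2, where the smallest p possible is 0.1, so this test cannot pass 0.05 with 3 libraries per group. Across 20685 genes the BafA1 change correlated with the change from hESC to the mean of both NPC groups at r = 0.04 and rho = 0.15, against r of -0.0144 to 0.0564 and rho of -0.00909 to 0.0200 in 10 simulations of unchanged groups. The covariance was 0.0855, against -0.00164 to 0.00655. The simulations gave all libraries the mean of control NPC, and so held no change from hESC to NPC. Their ranges are therefore no measure of what an ineffective treatment would give on the real axis. The mean of both NPC groups also holds part of the BafA1 change, which adds to the covariance. Against control NPC minus hESC, r was -0.16, rho -0.0851 and the covariance -0.329, but there the shared control libraries lower the values. The direction along the axis was thus not settled. With an NPC library left out rho stayed at 0.111 to 0.162, while the signs of r and of the covariance changed without control replicate 1 (r = -0.0139, covariance -0.0326) or 2 (-0.0188 and -0.0456). Both were higher without BafA1 replicate 1 (0.0895 and 0.227), 2 (0.0634 and 0.154) or 3 (0.110 and 0.263). Of genes called in both contrasts, 1357 were higher in both (1420 for independent lists) and 1298 lower in both (1350). Another 1617 genes were lower in control NPC than in hESC and higher with BafA1 (1360), and 1572 were higher in control NPC and lower with BafA1 (1409). With the replicate block the same directions no longer fell short (1333 against 1331 and 1307 against 1282). The opposite directions stayed above independence with the block (1544 against 1277 and 1491 against 1337). With DESeq2, over 31373 genes, the same directions lay above independence (1348 against 939 higher and 1441 against 981 lower in both). So did the opposite ones (1780 against 1019 and 1455 against 903). The comparison with independence thus depends on the setting and the genes counted. The control libraries could not be divided into groups of at least 2, and part of the excess of opposite directions may come from these shared libraries.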

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

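The GC and length correction, its combination with the replicate block and the block with an estimated correlation were chosen after the results were seen; the other tests here were set earlier. The number of changed genes stayed within 1.5 times its value in all settings except those that raise the threshold or test fewer genes. With a test against a 1.5-fold change it was 1690 for BafA1 NPC against control NPC, 7627 for control NPC against hESC and 9046 for BafA1 NPC against hESC. With a 2-fold minimum on the estimate it was 2258, 7041 and 8072. The stricter filter gave 8735 and 9596 in the comparisons with hESC, where only 12470 genes were tested. With each library left out in turn, the numbers were 6519 to 8747, 12144 to 13139 and 13510 to 14549. The number of gene lists called was 0 of 9 with an estimated correlation and 0 with the block as well for BafA1, and 5 and 4 of 16 for control NPC against hESC. Left-out libraries gave 9 to 10 and 15 to 18 lists. The correlation with the differentiation axis was r = -0.0188 to 0.110 with an NPC library left out. On the axis that shares the control libraries it was -0.16 (rho -0.0851, covariance -0.329). Simulated unchanged groups gave r = -0.507 and a covariance of -0.0674 on that axis. In them hESC were simulated like control NPC, so neither their r nor their covariance shows what an ineffective treatment would give on the real axis. The observed covariance was more negative than the simulated one, which for this reason does not settle a direction.

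Deviations of same-numbered libraries correlated weakly or not at all, at 0.05, -0.01 and 0.05 between control and BafA1 NPC, 0.11, 0.05 and 0.15 between hESC and control NPC (-0.147 to 0.0465 for different numbers), and -0.02, -0.05 and 0.26 between hESC and BafA1 NPC. Not every library correlated best with its own number. With the replicate block 8242, 13116 and 14295 genes were called, and 8290, 13399 and 14577 with the GC and length correction too. PAX6, SIX3 and SIM1 were not called with the block in BafA1 NPC against control NPC, where TUBB3 was called with the block and the correction together (-0.224, adjusted p = 0.0394). In control NPC against hESC the BMP and TGF-beta list was called by camera with the block (adjusted p = 0.0305). Without the block and with an estimated correlation it was not (adjusted p = 0.574).

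Of the log2 changes of named genes under these settings, 4321 kept their direction and side of the threshold, 119 lost the call, 15 gained it and 15 changed sign. None of those 15 estimates was past the threshold, and the cause was not tested. In BafA1 NPC against control NPC they were AXIN2 without control replicate 1 (0.0796; -0.134 without control replicate 3), SQSTM1 without BafA1 replicate 1 (0.0303) or control replicate 1 (0.0602; -0.18 without control replicate 3), MAP1LC3B under library size alone (-0.0259), log2(FPKM + 0.1) (-0.0512) and log2(FPKM + 1) with and without the filter (both -0.0498), LMX1A without BafA1 replicate 2 (0.0208) or 3 (0.134) or control replicate 3 (0.153; -0.339 without BafA1 replicate 1), OTX2 without BafA1 replicate 1 (-0.0154; 0.579 without control replicate 3), SHH without control replicate 3 (0.146; -0.469 without control replicate 1) and TUBB3 without control replicate 1 (0.109; -0.133 without control replicate 3). DVL3 in control NPC against hESC was at -0.0044 with DESeq2 and -0.0037 with its size factors in edgeR. Depth limits statements on genes near 0.0696 CPM or lower, among them POU5F1 in NPC, NANOG in BafA1 NPC and TH in control NPC.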

Other observations

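The 16 gene families described next were chosen after the data were examined. Genes of cytosolic ribosomal proteins stood higher in BafA1 NPC: 73 of 80 rose and 0 fell, with a median log2 change of 0.53 (0.40 under library size alone, 0.49 after removal of GC and length trends; camera adjusted p = 1.99e-10, but adjusted p = 0.520 with an estimated correlation). The share of counts from ribosomal protein genes overlapped between the groups. It was 8.61%, 11.8% and 10.5% in BafA1 replicates 1, 2 and 3, and 6.99%, 7.835% and 8.79% in control replicates 1, 2 and 3. Of 78 genes of mitochondrial ribosomal proteins 18 rose and 12 fell, with a median of 0.06 that was -0.07 under library size alone. All 6 tested metallothionein genes rose (median 2.81, camera adjusted p = 1.36e-09, but adjusted p = 0.134 with an estimated correlation). Of 41 collagen genes 19 rose and 3 fell (median 0.49), of 29 golgins 15 rose and 1 fell (median 0.59) and of 11 keratins 6 rose (median 0.58), with adjusted p = 0.232, 0.382 and 0.178 with an estimated correlation.

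Of 12 SR splicing factor genes 8 fell and 1 rose (median -0.68), of 22 nucleoporin genes 15 fell and 1 rose (median -0.34) and of 21 HNRNP genes 11 fell and 2 rose (median -0.28), with adjusted p = 0.178, 0.178 and 0.434 with an estimated correlation. Of 48 proteasome subunit genes 21 fell and 2 rose (median -0.16, camera adjusted p = 0.00937, but adjusted p = 0.714 with an estimated correlation). Among 478 ZNF genes, which encode zinc finger proteins, 211 fell and 45 rose, with a median of -0.29 that was -0.26 after removal of GC and length trends (camera adjusted p = 6.58e-07, but adjusted p = 0.225 with an estimated correlation). None of these medians changed sign under library size alone or after removal of GC and length trends, but that of the proteasome genes was -0.29 under library size alone and that of the HNRNP genes -0.18 after removal of the trends. In control NPC against hESC the ZNF genes went the other way by count, with 199 higher and 105 lower (camera adjusted p = 0.211). The families of translation initiation factors (18 rose and 11 fell of 55), complex I subunits (11 and 3 of 39), solute carriers (74 and 64 of 296) and histones (5 and 11 of 47) were not called, and kinesins were (15 fell and 3 rose of 38, camera adjusted p = 0.0496, or 0.157 after removal of GC and length trends, and adjusted p = 0.434 with an estimated correlation).

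Of the tests in the paragraphs that follow, those of other splits of genes, of TFRC, of single libraries and of the parts of the proliferation list were chosen only after the result was seen. Those of GC content and of other splits of lists were added later than the plan, but before their own results were seen. The 6 NPC libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 8586 changed genes and the highest of the others 1, and 1 of 10 splits gave as many as the real one. The same number, 1 of 10, was found for control NPC against hESC (13345 genes, highest other 0) and BafA1 NPC against hESC (14557 genes, highest other 0). Each other split mixed libraries of both groups, so that any difference between the groups counted as spread within them. Few calls were thus likely there in advance, and these splits cannot tell a difference from chance. GC and length trends may account for part of the BafA1 calls, since the control libraries differed in their GC trend. After removal of these trends 89.1% of the calls were still made with the same sign, which argues against them as the whole cause.

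The same kind of splits was applied to the counts of gene lists. For BafA1 NPC against control NPC the real split called 9 lists, the highest other split 14, and 3 of 10 splits, the real one among them, gave at least as many. For control NPC against hESC the real split called 16 lists and the highest other 14, so 1 of 10 gave as many. The other splits again mixed libraries of both groups and kept part of their difference, so these counts cannot tell a difference from chance. A preset correlation of 0.01 may be too low for lists whose members vary together between replicates, since with an estimated correlation the BafA1 comparison called 0 lists. The estimated correlation of the 9 called lists ran from 0.0331 (epithelial) to 0.698 (mitochondrially encoded), and was 0.645 for hypoxia. Fry, which does not compare a list with other genes, called each of these 9 lists (adjusted p = 0.00151 to 0.0153). It also called the hindbrain and spinal, ventral and lysosomal lists, which camera did not call. With 8586 of 20685 genes called, a list can pass fry without standing out from other genes.

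The rise of the hypoxia list was weighed against technical and biological explanations. A GC or length trend is argued against by the median of the list, 1.48 after removal of these trends and 1.501 before. A single aberrant library is argued against by at least 24 of 26 members called higher with any 1 of the 6 NPC libraries left out. Loss of lysosomal acidification can starve cells of iron and so stabilise hypoxia-inducible factors, and iron starvation at harvest would raise TFRC, but TFRC was lower in BafA1 NPC (-0.70, adjusted p = 1.60e-04). An effect of BafA1 that outlasts the exposure, earlier iron shortage, and differences in cell density, oxygen or handling between the dishes all remain candidate explanations, which these libraries cannot separate.

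The fall of the proliferation list may reflect lower expression of genes of the G1/S transition more than of its other members, a division made after the values were seen. All 13 G1/S members (MCM2 to MCM7, PCNA, E2F1, CCNE1, CCNE2, RRM2, TYMS and CDC6) fell, with a median of -0.72. Of the other 17 members 5 fell and 2 rose, with a median of -0.15. The difference of medians was -0.57, a description of these genes and not a test of the division. Whether fewer cells entered S phase, or the same cells held less of these transcripts, was not tested.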
